A study of Escherichia coli with 3 samples.

How the data were processed

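RNA was measured in 3 cultures of Escherichia coli K-12 MG1655, 1 library per group. The groups, taken from the labels, were cells without PABP, cells with PABP integrated into the chromosome and cells with PABP on a pBAD plasmid. Per the labels' protocols, cells grew at 37 °C in Luria Bertani broth and were harvested at an optical density at 600 nm of 0.6, while the series' design text gives 0.5. RNA was extracted with Trizol, and 4 μg of total RNA was depleted of ribosomal RNA with a RiboMinus kit. Libraries were made from 100 ng of depleted RNA with a strand-specific kit and 10 cycles of PCR and were sequenced as read pairs of 75 bases.

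The authors deposited 2 tables, 1 for each PABP strain against the same control library, and each table is divided into sheets of higher, lower and similar transcripts and of transcripts listed in 1 library only. Values in them are FPKM (fragments per kilobase of transcript, scaled to the total of mapped fragments), which per the submitters' processing notes the authors obtained with TopHat2, Cufflinks and Cuffdiff. The log2 fold changes in the authors' tables are the log2 of the strain's FPKM over the control's, with no pseudocount. The p-value and q-value columns are the authors' own, from a comparison of 1 library with 1 library. The genome build, the annotation and whether fragments were assigned by strand are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, as are genes that share a locus with another in the files, which held 971 of the 3522 transcripts of the chromosomal table and 974 of the 3483 of the plasmid table. Coordinates are given as in the files, counted from 1. Names were matched to current or older symbols of the RefSeq annotation of assembly ASM584v2, used for names, gene classes and the order of neighbouring genes only, for 3513 transcripts of the first table and 3474 of the second. The 2 tables were scaled separately: the control's FPKM in the plasmid table was 1.02 times that in the chromosomal table for 3329 transcripts, with a range of 1.01708 to 1.01719. No transcript had under 1.67 FPKM in its higher library in the chromosomal table or under 1.78 in the plasmid table, so transcripts low in both libraries are not covered.

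For each gene, log2((FPKM + 1)/(FPKM + 1)) was computed for chromosomal PABP over no PABP, plasmid PABP over no PABP and, with each strain set against the control value of its own table, plasmid PABP over chromosomal PABP. The pseudocount of 1 FPKM makes the ratio of low genes smaller than it was. Genes with at least 10 FPKM in either library of a comparison were kept, and those with a ratio of at least 2-fold were counted. A gene under 10 FPKM in 1 library was thus kept only where it reached 10 in the other, which largely set its direction. With 1 library per group there is no replicate check of any difference, no p-value was computed across genes, and higher and lower describe these libraries. In the plasmid table, 63 transcripts listed as found in the plasmid strain only and 45 listed as found in the control only were left out of the plasmid comparisons, because their values went against the column names. The design, the lists and the rule for named genes were set before the data were examined, whereas leaving out these 2 sheets was decided after seeing them.

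Fixed lists numbered 29. They covered general stress (the regulon of RpoS), acid resistance, heat shock, envelope stress, oxidative stress, the SOS response, cold shock, stationary phase and ribosome hibernation, polyadenylation and RNA decay, mRNAs studied as substrates of poly(A) polymerase I, ribosomal proteins, translation factors, flagella and chemotaxis, curli and type 1 fimbriae, the TCA cycle, aerobic respiration and ATP synthase, anaerobic respiration and fermentation, glycolysis, uptake of alternative carbon sources, the arabinose regulon, biosynthesis of amino acids and of nucleotides, iron uptake, cell division and shape, toxin-antitoxin systems, lambdoid prophage genes, neighbours of the lambda attachment site, ribosomal RNA, and small regulatory and stable RNAs. For each list the median log2 ratio of its kept genes was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists drew on all kept genes, ribosomal protein genes included, and ranks without those genes were not computed. A list was said to stand apart below percentile 2.5 or above percentile 97.5, as a description of these libraries. Lists left with too few kept genes were not ranked. Some genes belong to more than 1 list, such as infA and infC, which are in the cold shock and translation factor lists. Likewise gadE is in the general stress and acid resistance lists and fumC in the oxidative stress and TCA cycle lists. Lists that stand apart are therefore not independent results.

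Named genes were chosen per comparison among protein-coding genes with a symbol, 1 entry and at least 10 FPKM in either library. They were the 10 with the largest and the 10 with the smallest log2 ratio and the 2 highest and 2 lowest members of each list. Whatever their values, rpoS, pcnB, pnp, rne, hfq, araC, araB, the PABP transgene and gal and bio genes beside the lambda attachment site were added; the value of 1 such gene is not reported here.

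Depth was recovered from the FPKM values, which in each library moved in steps set by gene length and 1 fragment. Over genes of at least 300 nt alone at their locus, 97.6% of values under 10 fragments in the library without PABP, 98.7% with chromosomal PABP and 96.7% with plasmid PABP were whole within 0.05 fragments. This gave 1263135, 1183557 and 1007559 fragments over 2281, 2288 and 2239 genes, with medians of 76, 73 and 73 fragments per gene and fitted mean fragment lengths of 197.6, 182.8 and 208.5 nt. For these genes the 95% interval of the log2 FPKM ratio was computed from both fragment counts (exact Clopper-Pearson, no pseudocount). PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Genes shorter than 300 nt or sharing a locus have no interval.

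The steps were tested on simulated data. For ratios and lists these used a set spread of 0.5 on the log2 scale, independent per gene and without counting error. No replicate gives the true spread, so the shares below hold for that setting only. Fragment counts under 10 were recovered in 100% of simulated genes. Of genes changed 1.5-, 2-, 4- and 8-fold among the 2496 kept genes of the chromosomal comparison, 88, 100, 100 and 100% had the right direction and 14, 52, 98 and 100% a ratio of at least 2-fold. For the 2438 genes of the plasmid comparison these shares were 86, 96, 100 and 100% and 18, 50, 96 and 100%. Of 200 unchanged lists, 2.5% in the chromosomal and 6.5% in the plasmid simulation lay outside the percentile limits, and a list of 40 genes shifted by 0.5 on the log2 scale had percentile 100 in both.

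Because both comparisons share the control library, 100 sets of unchanged strains were simulated against it, with counting error alone and with an added spread of 0.5 on the log2 scale. Each result was recomputed with a pseudocount of 0.1 or 5 FPKM, with no minimum or one of 50 FPKM, centred on the median, rescaled to equal FPKM totals, with genes of at least 300 nt, without shared loci, with the authors' log2 values, and with 1 value per run of neighbouring genes of a list. The totals made equal left out ribosomal, transfer and small RNAs, so they are not the totals of the whole libraries. Added after seeing the data were both readings of the left-out sheets, a minimum of 20 recovered fragments, and the correlation without ribosomal proteins and translation factors. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.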

Results

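Transcript levels were measured by RNA sequencing in Escherichia coli K-12 MG1655, a laboratory strain, with and without a mammalian poly(A)-binding protein (PABP). In mammalian cells this protein binds the poly(A) tails of messenger RNAs. In E. coli, poly(A) polymerase I, the product of pcnB, adds short tails to many RNAs. The 3 libraries came from cells without PABP, cells with PABP placed in the chromosome by phage lambda and cells with PABP on a pBAD plasmid, a vector that carries the arabinose-responsive regulator gene araC. The series' title ties PABP to the general stress response, the set of genes that the sigma factor RpoS turns on in starved or stressed cells. Recovered depth was 1263135 fragments without PABP, 1183557 with chromosomal PABP and 1007559 with plasmid PABP, over genes of at least 300 nt alone at their locus. With 1 library per group, no difference below has a replicate check. The library without PABP is labelled n/a for transformation, so carrying the vector or the integrated phage has no control. The counting intervals given with ratios cover counting error only. Gene positions are on the single E. coli chromosome as in the authors' files, and the build is not given in the sources used here. The level of the PABP transgene was not analysed here, since 0 transcripts in the tables were named for it.

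With PABP in the chromosome, genes of the general stress regulon and the TCA cycle were higher and genes for the translation machinery lower than without PABP. The gene rpoS (2866559 to 2867551) had 189 FPKM against 60.9, a log2 ratio of 1.62 with a counting interval of 1.44 to 1.83 from 905 and 295 fragments. Of 52 listed genes of the RpoS regulon 44 were kept, of which 31 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.45. All 54 ribosomal protein genes were at least 2-fold lower, with a median of -3.36, and 14 of 18 TCA cycle genes were higher, with a median of 1.71. Genes for uptake and breakdown of galactarate (gar) and of D-serine (dsdX) had the largest ratios among genes long enough for a fragment count.

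Within the RpoS regulon, the 2 highest members were ycgB and yeaG, the latter a protein kinase gene, at 24.9 against 1.11 FPKM (log2 ratio 3.62) and 50.7 against 3.50 FPKM (3.52). The lowest were ecnB, at 17.9 against 25.6 FPKM, and gadE, an activator of acid resistance genes, at 50.4 against 57.1 FPKM with an interval of -0.58 to 0.22 that includes 0. In the stationary phase and ribosome hibernation list, 8 of 17 genes were higher and 1 lower (median 0.59). There raiA, which encodes a factor that inactivates ribosomes in resting cells, had 8948 against 737 FPKM (log2 ratio 3.60, interval 3.49 to 3.72), and spoT, an enzyme of the alarmone ppGpp, had 27.9 against 72.4 FPKM. Acid resistance genes were mixed, with 4 of 17 higher and 3 lower (median 0.65). The lysine decarboxylase genes cadB (60.3 against 9.53 FPKM) and cadA (94.4 against 24.8) were the highest there, and the arginine-agmatine exchanger gene adiC was the lowest (4.69 against 27.9).

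Genes of the translation machinery lay at the other end. In the ribosomal protein list, rplW, which shares its locus with rplD, had 70.9 against 2716 FPKM, and rplC (3452297 to 3452926) had 79.8 against 2578 FPKM (log2 ratio -5.00, interval -5.22 to -4.82). The least lowered was rpmE, at 261 against 982 FPKM. Of 13 translation factor genes, 12 were lower (median -2.44). The elongation factor G gene fusA had 237 against 2438 FPKM (log2 ratio -3.36), and the ribosome recycling factor gene frr had 222 against 337. Of 19 nucleotide biosynthesis genes, 17 were lower (median -1.98), led by guaB, which encodes IMP dehydrogenase, at 5.14 against 63.0 FPKM. Of 14 kept flagellar and chemotaxis genes, from 40 listed, 11 were lower (median -1.85). The sigma factor gene fliA had 1.26 against 13.5 FPKM, while flagellin, fliC, had 8.88 against 10.1. Both passed the minimum FPKM through the control only. Cold shock genes were lower in 12 of 13 cases (median -1.86), as for the initiation factor gene infA at 84.8 against 562 FPKM. That gene is in the translation factor list too. In the curli and fimbriae list 6 of 8 kept genes were lower (median -1.97, or -0.45 with 1 value per run of neighbouring genes). The 2 highest and 2 lowest were all fim genes of type 1 fimbriae, so no curli result is given. Among them fimF had 0.971 against 15.2 FPKM.

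Lists of metabolic genes differed in direction. In the TCA cycle list, the fumarase genes fumC (55.1 against 5.45 FPKM, overlapping a neighbour) and fumA (245 against 29.9 FPKM, log2 ratio 2.99) were the highest, and fumB was at 111 against 140 FPKM. Of 38 genes of anaerobic respiration and fermentation, 8 were higher and 10 lower (median 0.26, or -0.22 with 1 value per run of neighbouring genes): the nitrite reductase gene nrfA had 226 against 15.9 FPKM, and the formate channel gene focA had 40.6 against 389. Of 39 genes for uptake of alternative carbon sources, 8 were higher and 4 lower (median 0.28, or 0.07 with a minimum of 50 FPKM), with the tryptophanase gene tnaA at 10714 against 1030 FPKM and the beta-galactosidase gene lacZ at 139 against 14.1. In the gar genes, garL (3272787 to 3273557) had 681 against 1.43 FPKM, a log2 ratio of 8.13, with an interval of 7.67 to 10.52 that is wide because the control held 5 fragments. For garR the levels were 788 against 5.02 FPKM, for garK 712 against 7.27, for garD 709 against 8.84 and for garP 145 against 0.722. The D-serine transporter gene dsdX had 161 against 0.576 FPKM, from 1100 and 4 fragments. The putative transporter gene yhjX (3710799 to 3712007) had 4.45 against 534 FPKM (log2 ratio -6.62, interval -7.51 to -6.36).

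Genes tied to RNA decay and to the constructs were also measured. Of 18 genes of polyadenylation and RNA decay, 1 was higher and 7 lower (median -0.58, percentile 26.2), so the list did not stand apart. The ribonuclease II gene rnb had 8.01 against 65.2 FPKM, polynucleotide phosphorylase (pnp) 199 against 460, ribonuclease E (rne) 48.8 against 93.4, and rraA, which encodes an inhibitor of ribonuclease E, 600 against 268. The RNA chaperone gene hfq had 632 against 567 FPKM, with an interval of -0.04 to 0.35. The poly(A) polymerase gene pcnB had 13.2 against 66.2 FPKM, at a locus it shares with folK, so its level is uncertain. Of the 6 mRNAs studied as substrates of poly(A) polymerase I, 0 were higher and 3 lower (median -0.70, percentile 43.7), 2 of them the ribosomal protein genes rpsO and rpsT, with rpsO at 169 against 1075 FPKM and lpp at 9514 against 7471. In the arabinose regulon all 4 kept genes of 9 listed were higher (median 2.44). The 4, araC, araF, araG and araH, had under 10 FPKM without PABP, so the minimum set their direction and bears on their rank. The gene araC had 65.6 against 9.88 FPKM (log2 ratio 2.61, interval 2.25 to 3.24), and araF had 14.5 against 1.87. The kinase gene araB was at 3.34 against 1.53 FPKM. The list of neighbours of the lambda attachment site had a median of 0.42. That median was negative with no minimum FPKM or 1 value per run of neighbouring genes, and 1.29 (percentile 99.2) with a minimum of 50 FPKM. Of the list's 14 kept genes, 4 were higher and 2 lower. There galT had 190 against 67.1 FPKM, galK and galM share a locus and had 267 against 78.7 and 190 against 105, and ybhC (805998 to 807281) had 0.922 against 40.4. Of the bio genes, bioB had 1.18 against 3.31 FPKM and bioA 2.60 against 2.86.

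Toxin-antitoxin genes were higher in 8 of 16 cases and lower in 0 (median 1.08, or 0.25 without shared loci), with prlF, at a shared locus, at 129 against 23.2 FPKM. Heat shock genes (1 higher and 2 lower of 25, median -0.13), SOS genes (3 and 1 of 18, -0.31), cell division genes (0 and 7 of 23, -0.35) and lambdoid prophage genes (0 and 1 of 6, -0.32) had medians whose sign turned with rescaling to equal totals. In these lists the chaperone gene clpB, at a shared locus, had 183 against 51.3 FPKM, dinD 27.9 against 10.7, mreC 8.81 against 63.6, and borD 8.78 against 191. Envelope stress genes were lower in 11 of 25 cases and higher in 0 (median -0.74, percentile 5.62), as for dsbA at 45.3 against 211 FPKM. Oxidative stress genes were higher in 5 of 17 cases (median 0.35, negative without shared loci), with acnA at 46.7 against 5.30 FPKM. In aerobic respiration, 5 of 30 genes were higher and 9 lower (median -0.61), with the oxidase gene cyoA at 265 against 30.6 FPKM and the ATP synthase gene atpA at 162 against 1069. Glycolysis had 3 of 18 genes higher and 8 lower (median -0.95), with the glucose transporter gene ptsG at 13.7 against 150 FPKM. Amino acid biosynthesis had 6 of 28 higher and 1 lower (median 0.27), with metE at 77.2 against 5.89 FPKM. For iron uptake 0 of 5 genes passed 2-fold (median 0.36), for ribosomal RNA 1 of 2 was lower (median -0.96), and for small RNAs 3 of 13 were higher and 2 lower (median 0.34). Ribosomal RNA was depleted before sequencing, so what was left does not give its level in the cells.

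In all, 506 of 2496 kept genes were at least 2-fold higher and 744 lower with chromosomal PABP. For 1648 genes with fragment counts, 236 had an interval wholly above 2-fold and 374 wholly below. The median over kept genes was -0.27, so ratios may be read against that shift. Centred on the median, 641 genes were higher and 604 lower. Rescaled to equal FPKM totals outside ribosomal, transfer and small RNAs, 751 were higher and 559 lower. The share of higher genes among those beyond 2-fold thus moves from 40.5% to 51.5% and 57.3%. Against random lists, 8 of 28 ranked lists stood apart above and 6 below. The general stress and TCA cycle lists had percentile 100, ribosomal proteins and nucleotide biosynthesis 0, flagella 0.06 and translation factors 0.12. Toxin-antitoxin genes had percentile 99.8, alternative carbon sources 99.1, acid resistance 99.0, stationary phase 98.8, the arabinose regulon 98.3, anaerobic respiration 97.9, cold shock 2.39 and curli and fimbriae 1.15. The general stress, TCA cycle, ribosomal protein and translation factor lists stood apart under every setting tried, and each of the other 10 lost its place under at least 1 setting, with 6 lists besides general stress left when runs of neighbouring genes counted once. Named genes with at least 10 FPKM in 1 library and listed at 0 in the other were all under 300 nt: ynhF (3140 against 0 FPKM), pmrR (1570), ivbL (956), relB (20.6) and sra (207) in the strain, and uof (4763), ecnA (74.7) and mgrB (29.0) in the control. For ynhF, pmrR and ivbL those values are 2, 1 and 2 times a step shared by genes of the same length, so they can rest on as few fragments. The authors' deposited table gives 730 transcripts as higher and 930 as lower, 211 with a p-value under 0.05 and 0 with a q-value under 0.05, its lowest q-value being 0.176.

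**Figure D1:**
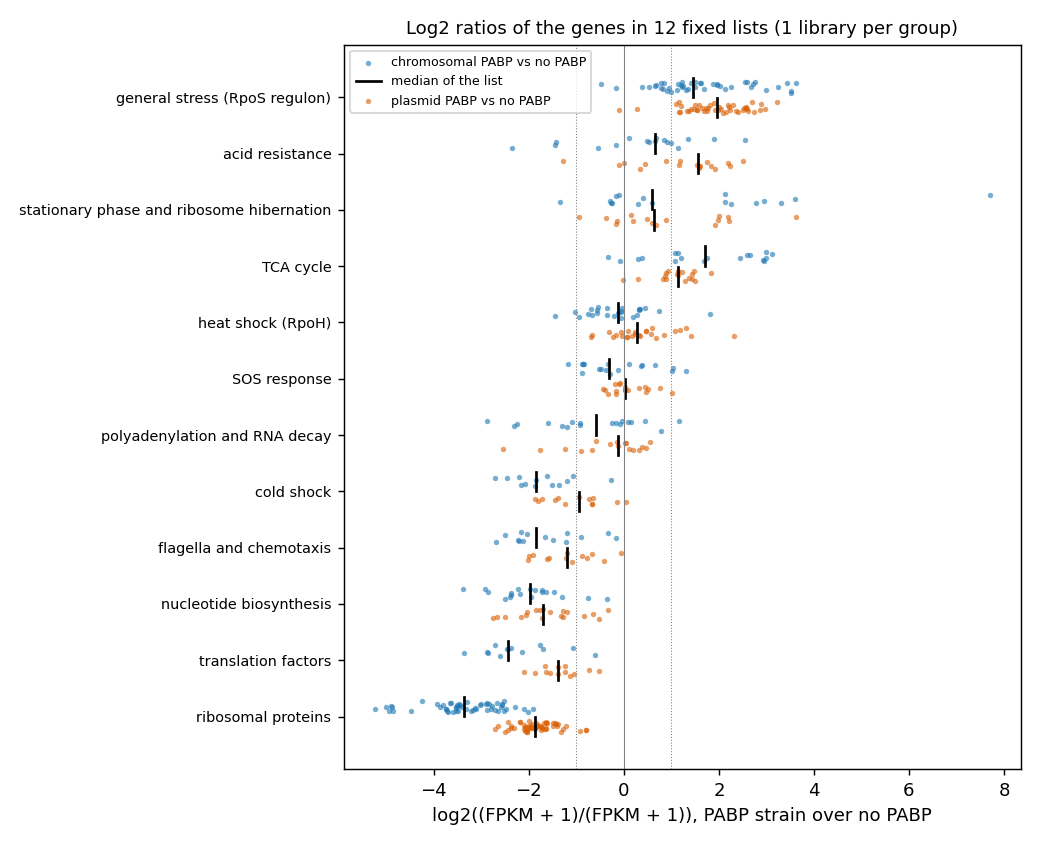
Log2 ratios (horizontal axis, log2((FPKM + 1)/(FPKM + 1)) over the library without PABP) of the kept genes in 12 of the fixed lists, for chromosomal PABP (blue) and plasmid PABP (orange), 1 point per gene, with black bars at list medians and dotted lines at 2-fold. RpoS regulon medians lie at 1.45 and 1.95 and ribosomal protein medians at -3.36 and -1.86; the point furthest right is sra, listed at 0 without PABP.

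With PABP on the plasmid, the RpoS regulon was again higher and the translation machinery lower than without PABP. The sigma factor gene rpoS had 195 against 61.9 FPKM (log2 ratio 1.64, counting interval 1.46 to 1.85, 818 and 295 fragments). Of 51 listed genes of its regulon 46 were kept, of which 44 were at least 2-fold higher and 0 lower, with a median of 1.95. Acid resistance genes were higher in 12 of 18 cases and lower in 1 (median 1.56). Ribosomal protein genes were lower in 51 of 54 cases (median -1.86), and TCA cycle genes were higher in 11 of 18 (median 1.14).

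The highest members of the RpoS regulon were yeaG, at 41.3 against 3.56 FPKM (log2 ratio 3.21, interval 3.05 to 4.07), and yahO, at 112 against 13.6. Its kept members short of 2-fold were sodC, at 26.8 against 22.1 FPKM, and gadE, at 53.8 against 58.1, both with intervals that include 0. Among acid resistance genes, the glutamate antiporter gene gadC had 56.0 against 8.99 FPKM and the glutamate decarboxylase gene gadA 50.3 against 9.86, while adiC had 11.1 against 28.4. In the stationary phase list, 6 of 16 genes were higher and 0 lower (median 0.64). The ribosome modulation factor gene rmf had 3703 against 300 FPKM (log2 ratio 3.62), raiA had 3491 against 750 (2.22), and spoT had 37.6 against 73.6.

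Lower genes again included the translation machinery. The ribosomal protein genes rplC and rpsJ had 397 against 2622 FPKM (log2 ratio -2.72) and 594 against 3727 (-2.65), and rplT had 952 against 1651. Translation factor genes were lower in 11 of 13 cases (median -1.39), with the release factor gene prfC at 17.9 against 79.7 FPKM. Nucleotide biosynthesis genes were lower in 15 of 19 (median -1.70), with pyrC at 2.23 against 20.8 and guaB at 9.23 against 64.1 FPKM. Flagellar genes were lower in 8 of 13 (median -1.19), with flgG at 4.24 against 20.3 FPKM. The smallest ratio belonged to yhjX, at 2.43 against 543 FPKM (log2 ratio -7.31, interval -8.71 to -7.03). The operon of the anaerobic glycerol-3-phosphate dehydrogenase, glpA, glpB and glpC, whose genes share a locus, had 8.04 against 186, 8.19 against 141 and 5.53 against 115 FPKM, and the aerobic enzyme's gene glpD had 8.80 against 86.8. Also among the 10 lowest were the putrescine importer gene plaP (1.30 against 25.7 FPKM), the magnesium transporter gene mgtA (10.8 against 94.5) and the peptide transporter gene dtpA (7.81 against 63.7).

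Genes of melibiose and lactose use were among the 10 highest. The alpha-galactosidase gene melA (4341911 to 4343266) had 78.3 against 3.89 FPKM, a log2 ratio of 4.02 with an interval of 3.77 to 4.95. In the lac operon lacZ had 215 against 14.3 and lacY 35.8 against 3.16 FPKM. The arginine exporter gene argO had 81.8 against 4.95, the dipeptide-binding protein gene dppA 214 against 22.9, nanM of sialic acid metabolism 27.7 against 2.20 and garL 22.6 against 1.46. In the TCA cycle the citrate synthase gene gltA had 115 against 31.7 FPKM (log2 ratio 1.82), and fumB had 141 against 142. Of 39 alternative carbon source genes, 8 were higher and 7 lower (median -0.05), and of 38 anaerobic genes 9 were higher and 3 lower (median 0.16, negative without shared loci), with nrfA at 77.4 against 16.2 and focA at 68.3 against 396 FPKM.

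Of 17 genes of polyadenylation and RNA decay, 0 were higher and 3 lower (median -0.13, percentile 46.6). That median changes sign when libraries are rescaled to equal totals. The gene rnb had 10.5 against 66.4 FPKM, pnp 292 against 468, rne 102 against 95.01 and hfq 849 against 577. Of the 6 substrates of poly(A) polymerase I, 1 was higher and 2 lower (median 0.15, percentile 86.0), namely trxA at 743 against 355 FPKM and the ribosomal protein genes rpsO at 357 against 1094 and rpsT at 238 against 859. The gene pcnB was on a sheet left out of the plasmid comparisons. The pBAD regulator gene araC had 53.6 against 10.0 FPKM (log2 ratio 2.31, interval 1.92 to 2.94) and was the only kept gene of the arabinose regulon, while araB had 5.40 against 1.56. Of 15 neighbours of the lambda attachment site, 1 was higher and 2 lower (median 0.49): gpmA had 172 against 69.4 FPKM, ybhC 16.9 against 41.1, and ybhA 8.59 against 23.9, with galT at 119 against 68.2.

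Among the remaining lists, cold shock genes were lower in 6 of 13 cases (median -0.94), with cspE at 3847 against 13398 FPKM. Heat shock genes were higher in 5 of 26 (median 0.28), with clpB at 265 against 52.2 FPKM and htpG at 187 against 69.4. Oxidative stress genes were higher in 5 of 17 (median 0.52), with sufB at 14.3 against 1.30 FPKM. Toxin-antitoxin genes were higher in 4 of 15 and lower in 1 (median 0.57), and amino acid biosynthesis genes in 3 and 1 of 26 (median 0.49), with metE at 20.7 against 5.99 FPKM. Envelope stress (3 higher and 1 lower of 26, median 0.07), the SOS response (1 and 0 of 18, 0.02), curli and fimbriae (0 and 0 of 8, -0.51, positive with 1 value per run), iron uptake (1 and 1 of 5, -0.82), ribosomal RNA (0 and 0 of 2, -0.62, as left after depletion) and small RNAs (3 and 0 of 11, 0.19) had few genes beyond 2-fold. Medians near 0 whose sign turned with rescaling were those of aerobic respiration (0 and 4 of 29, -0.11), glycolysis (3 and 1 of 18, -0.08), cell division (0 and 5 of 23, -0.01) and prophage genes (2 and 2 of 9, -0.03), as well as the RNA decay and alternative carbon source lists above.

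Across 2438 kept genes, 373 were at least 2-fold higher and 426 lower, with a median of -0.03. Of 1626 genes with fragment counts, 154 had an interval wholly above 2-fold and 183 wholly below. Rescaled to equal FPKM totals outside ribosomal, transfer and small RNAs, 601 were higher and 276 lower. This moves the share of higher genes among those beyond 2-fold from 46.7% to 68.5% and the median over kept genes to 0.31. Of 27 ranked lists, 5 stood apart above and 4 below. The general stress, acid resistance and TCA cycle lists had percentile 100, stationary phase 99.7, amino acid biosynthesis 97.8, ribosomal proteins and nucleotide biosynthesis 0, flagella 0.11 and translation factors 0.55. Amino acid biosynthesis lost its place under 6 settings and nucleotide biosynthesis with a minimum of 50 FPKM (percentile 2.91). Flagella lost theirs with 1 value per run of neighbours (2.64) and could not be ranked with a minimum of 50 FPKM. The other 6 lists stood apart under every setting tried. The authors' deposited table gives 610 transcripts as higher and 565 as lower, 209 with a p-value under 0.05 and 0 with a q-value under 0.05, its lowest q-value being 0.174.

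**Figure D2:**
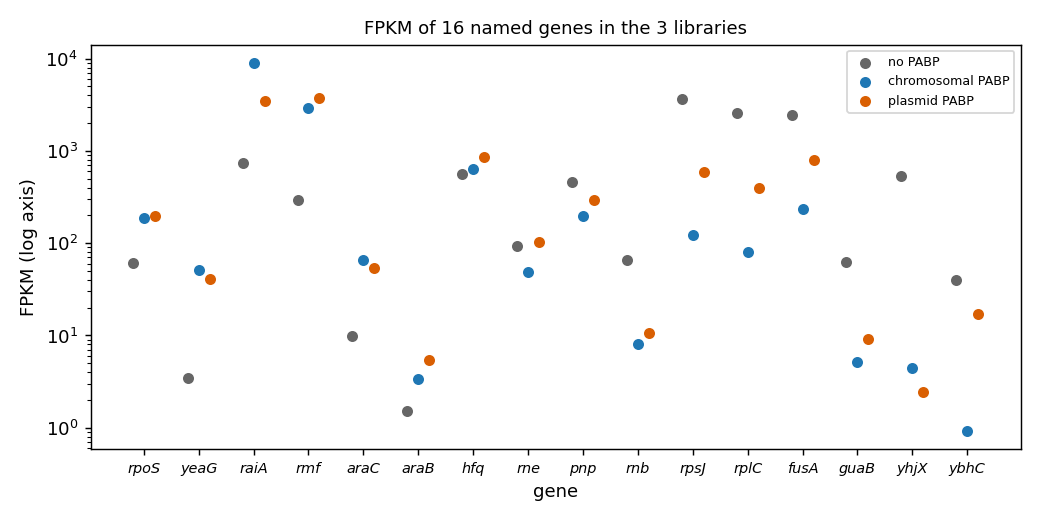
FPKM (vertical log axis) of 16 genes named in the text in the library without PABP (grey, as scaled in the chromosomal table), with chromosomal PABP (blue) and with plasmid PABP (orange), 1 point per library. The gene rpoS lies at 60.9, 189 and 195 FPKM and rplC at 2578, 79.8 and 397 FPKM.

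Between the strains, ribosomal protein genes were higher and galactarate genes lower with the plasmid than with the chromosomal construct. Ribosomal protein genes were at least 2-fold higher in 45 of 54 cases and lower in 0 (median 1.48), with rplV at 459 against 59.9 FPKM (log2 ratio 2.89, interval 2.49 to 3.36). The gar genes were lower, with garL at 22.6 against 681 FPKM (-4.87, interval -5.31 to -4.59). The level of rpoS was 195 against 189 FPKM (0.02, interval -0.12 to 0.16), and 6 of 47 RpoS regulon genes were higher and 1 lower (median 0.35, percentile 87.5), so that list did not stand apart.

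Higher lists with the plasmid were those of acid resistance, with 7 of 18 genes higher and 1 lower (median 0.90), envelope stress, with 5 of 26 higher (0.72), and heat shock, with 5 of 26 higher (0.51). The efflux genes mdtE and mdtF had 20.1 against 4.68 and 30.5 against 7.91 FPKM, the periplasmic protease gene degP 66.4 against 12.7 (log2 ratio 2.28) and the chaperonin gene groS 389 against 130. Translation factor genes were higher in 5 of 13 (0.84), with fusA at 787 against 237 FPKM, and glycolysis genes in 7 of 18 (0.83), with eno at 646 against 237. In the curli and fimbriae list 6 of 7 kept genes were higher (1.37), with the type 1 fimbrial gene fimC at 38.0 against 13.1 FPKM. Of aerobic respiration genes, 10 of 30 were higher and 5 lower (0.48), with atpG at 658 against 203 and cyoA at 26.8 against 265 FPKM. Among single genes, the trehalose genes treB and treC had 803 against 64.8 and 495 against 51.3 FPKM, glmS, an mRNA studied as a substrate of poly(A) polymerase I, had 271 against 64.9, and ybhC had 16.9 against 0.922.

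Lists lower with the plasmid were the TCA cycle, with 7 of 18 genes lower (median -0.44), iron uptake, with 3 of 5 lower and 1 higher (-1.18, or -0.12 with no minimum FPKM), and the arabinose regulon, in which none of 4 passed 2-fold (-0.50). There fumA had 75.4 against 245 FPKM, exbD 12.8 against 36.8, feoA 26.7 against 11.5, and araG 8.17 against 16.6. Genes for glucarate use, gudP and gudX, had 2.62 against 64.5 and 3.97 against 74.3 FPKM, dsdX 12.4 against 161 and raiA 3491 against 8948 (log2 ratio -1.38). The genes ecnA, tpr, ccmD, aaeX and mdtI were listed at 0 with chromosomal PABP and had 99.0, 29.7, 18.2, 13.6 and 13.3 FPKM with the plasmid. Genes at 0 with the plasmid could not enter, since the sheets of transcripts listed in 1 library only were left out of that table. Differences from 0 can thus appear in this direction only. At 126 nt ecnA is shorter than the fitted fragment lengths, so a few fragments can give such a value. In the RNA decay list 2 of 17 genes were higher (0.10, a median that changes sign when ratios are centred), with rne at 102 against 48.8 FPKM (log2 ratio 1.03, interval 0.92 to 1.16), and pnp was at 292 against 199.

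Kept genes numbered 2356, of which 324 were at least 2-fold higher and 164 lower, with a median of 0.24, and of 1582 with fragment counts 103 had an interval wholly above 2-fold and 65 wholly below. Centred on the median, 198 were higher and 253 lower, which moves the share of higher genes among those beyond 2-fold from 66.4% to 43.9%. Of 28 ranked lists 7 stood apart above and 3 below. Ribosomal proteins, envelope stress, translation factors and glycolysis stood apart under every setting tried, whereas acid resistance, heat shock, curli and fimbriae, the TCA cycle, the arabinose regulon and iron uptake did so under some settings only. The 2 tables were scaled separately, and levels set across them rest on the shared control.

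Across 2524 genes kept in either comparison, the log2 ratios of the strains against the shared control had a Pearson correlation of 0.84 and a Spearman correlation of 0.86, as a description across genes, which are not independent replicates. At least 2-fold higher in both were 320 genes and lower in both 381, and 5 genes passed 2-fold in opposite directions. For 231 of the 320 and 337 of the 381 genes the ratio with chromosomal PABP was the larger in size, as for rplC. Unchanged strains simulated against the same control gave a correlation of 0.50 and a covariance of 0.03 from counting error, or 0.26 with an added spread. The 1692 genes simulated had an observed correlation of 0.87 and covariance of 1.53. Sharing the control gives 0.50 by itself where all libraries spread alike, and the simulated covariances follow from the spread that was set. The simulation therefore cannot say how far the real control departs. With 1 control library the controls could not be split, so the part of the observed correlation and covariance that comes from the shared control is not known.

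**Figure D3:**
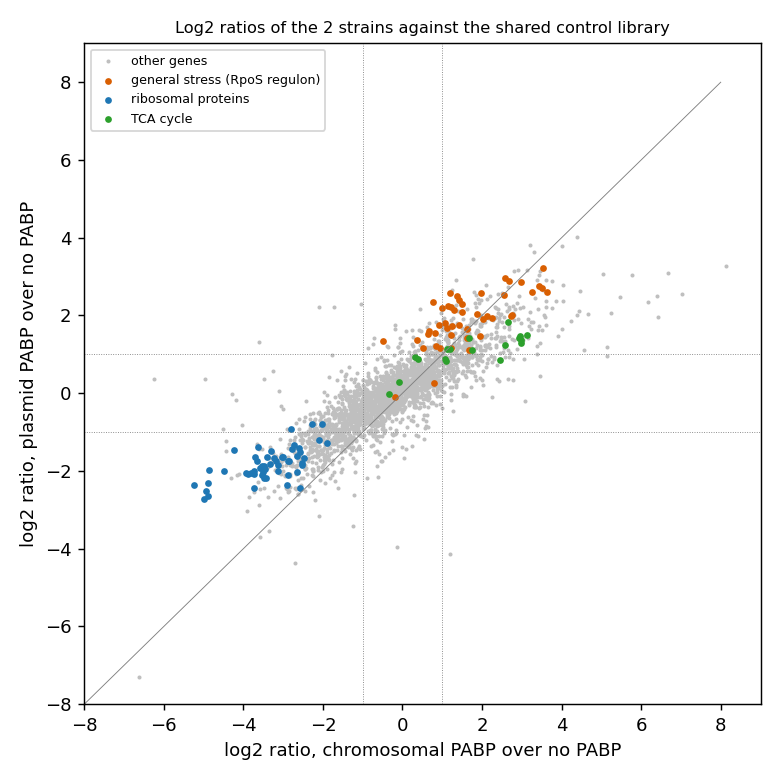
Log2 ratio with plasmid PABP (vertical axis) against that with chromosomal PABP (horizontal axis), both over the same control library, for 2524 genes, 1 point per gene, with the RpoS regulon (orange), ribosomal proteins (blue) and TCA cycle (green) marked, dotted lines at 2-fold and a line of equal ratios. Ribosomal protein genes lie above that line, with medians of -3.36 and -1.86, and the correlation across genes is 0.84.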

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

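The tests of the 2 sheets of the plasmid table and of scaling between libraries were chosen only after the results they concern were seen.

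In 5 genes the strains lay on opposite sides of the shared control, each by at least 2-fold, and with 1 library per strain these differences were not tested. For glmY, a small RNA of amino sugar metabolism, the log2 ratio was -1.73 with chromosomal PABP and 2.22 with the plasmid, a difference of 3.94. For glpC the ratios were 1.19 and -4.15, a difference of -5.34. The difference was 4.31 for folK, 4.92 for tpr, which was listed at 0 with chromosomal PABP, and 3.33 for xisD-1. All but glmY share a locus with another gene, so the division of fragments between overlapping genes is uncertain there. No counting interval is given for glmY.

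A signal also appeared on the sheets of the plasmid table left out of the comparisons, with 63 genes listed as found in the plasmid strain only and 45 as found in the control only. All 63 values of the former equal the control's value in the chromosomal table times the constant between the tables, to a relative 0.0001, which argues against the values belonging to the libraries that the columns name, since 63 of these genes then have a control value above 0 elsewhere. Low values point the same way: on that sheet 9 of 9 values under 10 fragments were whole in the control's steps and 0 of 9 in the plasmid strain's, and on the other sheet 0 of 9 and 9 of 9. The 63 values are thus those of the control library, so the column name of that sheet is wrong. Of the 45 genes on the other sheet, 0 have a control value above 0 in the chromosomal table. There 27 of them were listed as found in the strain only and 18 are absent. Together with the steps, this argues that the column names of the 2 sheets are exchanged. The exchange was found and tested on the same data, and the steps cover only values under 10 fragments.

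The most extreme log2 ratios with chromosomal PABP belonged to genes shorter than the fitted fragment length. Of 20 coding genes under 150 nt, 8 (40%) were listed at 0 in 1 library and above 10 FPKM in the other, against 2 of 3104 (0.064%) of at least 300 nt. This is consistent with the explanation that 1 or a few fragments become a large FPKM where the gene is shorter than the fragments. An effect of PABP on these genes was not tested and stays open.

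Ribosomal protein genes were lower and RpoS regulon genes higher in both PABP libraries, the pattern seen in cultures that grow slowly or approach stationary phase. Scaling between libraries moves all genes by 1 factor, and the median of the RpoS regulon lay 4.81 log2 units above that of the ribosomal proteins with chromosomal PABP and 3.82 with the plasmid, which argues against scaling as its cause. A later stage of the culture might show as a lower copy number of genes near the replication origin, but the slopes of the ratio on distance from the origin were -0.077 and -0.030 log2 units per Mb over 1915 and 1871 genes, at percentiles 30.25 and 31.6 of 2000 rotations of the map. They met the bound set in advance against it, 0 or below, but lay within the spread of rotations, a condition added after the slopes were seen, so it stays open. With 1 library without PABP, labelled n/a for transformation, there was no control for the vector or for integration by lambda. Without a control matched for growth either, PABP itself, the construct that carries it and the stage of the culture cannot be told apart.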

How the results depend on the processing

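The readings of the 2 left-out sheets, the minimum of 20 recovered fragments and the correlation without ribosomal proteins and translation factors were chosen only after the data were seen. The RpoS regulon list kept its side of the percentile limits in each comparison under all settings run, and its median its sign, as did the sign of the correlation between strains. Counts of genes beyond 2-fold and of lists standing apart, and the correlation, stayed within their bounds (1.5 times, or 0.05 for the correlation) in 96 cases and moved past them in 18. A minimum of 50 FPKM left 283 genes higher and 441 lower with chromosomal PABP, 191 and 258 with the plasmid and 185 and 97 between the strains, since fewer genes enter. Under it 7 instead of 13 lists besides general stress stood apart with chromosomal PABP and 5 instead of 8 with the plasmid. A minimum of 20 fragments likewise left 330 higher and 481 lower with chromosomal PABP, and 238 higher with the plasmid and 202 between the strains. Rescaled to equal totals outside ribosomal, transfer and small RNAs, 601 genes were higher and 276 lower with the plasmid. Centred on the median, 198 were higher and 253 lower between the strains. Both follow from the shift each scaling applies. With 1 value per run of neighbouring genes, 6 instead of 13 lists stood apart with chromosomal PABP, and the median of anaerobic respiration turned from 0.26 to -0.22, since operons then weigh as 1 gene. Reading the left-out sheets by their column names, which their values argue against, lowered the correlation from 0.84 to 0.32. With the libraries exchanged it was 0.80. Of the other values, single lists and named genes, 3451 kept their place, 1346 moved by more than their counting interval or had none, 51 fell back inside the percentile limits or had too few genes to rank, 21 moved outside them and 1, anaerobic respiration, stood apart and turned sign. Settings that only change which genes enter cannot move a named gene's own ratio. Centring cannot move a list's percentile or the correlation. Such values are counted as kept or within bounds, so these tallies do not measure stability. Medians of lists that did not stand apart turned sign in 38 of 612 values, in 24 of 54 lists counted per comparison. Depth limits the ratios of genes with few fragments most, as the wide interval of garL shows. The minimum of 20 fragments was applied to counts of genes and named genes only, and 1 value per run to lists only. No paired analysis was possible because each group holds 1 library and nothing pairs samples beyond it.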

Other observations

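The genes in this part were chosen after their values were seen, and no test was run on them. Beyond the gar genes, the glucarate dehydratase gene gudD had 87.3 FPKM with chromosomal PABP, against 2.73 without PABP and 7.11 with the plasmid. The D-serine deaminase gene dsdA had 262, 5.95 and 28.7 FPKM in that order, and bssR, a regulator of biofilm formation, had 434, 6.99 and 66.3 FPKM. In sialic acid metabolism nanM had 26.5 FPKM with chromosomal PABP and 27.7 with the plasmid, against 2.17 without PABP, and the melibiose permease gene melB had 33.2 and 25.3 against 2.15 FPKM. The tryptophan transporter gene tnaB, beside tnaA, had 675 and 516 against 88.2 FPKM. Trehalose genes went the other way, with treB at 64.8 FPKM and treC at 51.3 FPKM with chromosomal PABP against 1502 and 861 FPKM without PABP, and 803 and 495 FPKM with the plasmid.

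Terminal oxidases and a small RNA circuit differed between the strains. Cytochrome bd genes cydA and cydB had 319 and 374 FPKM with chromosomal PABP, 566 and 679 without PABP and 717 and 934 with the plasmid, while cyoE of cytochrome bo had 26.03, 7.34 and 11.5 FPKM. The small RNAs glmY and glmZ had 229 and 540 FPKM with chromosomal PABP, 760 and 983 without PABP and 3601 and 2248 with the plasmid. The mRNA glmS, known to be activated by glmZ, was ordered in the same way, with 64.9, 167 and 271 FPKM. The small RNA csrB, which binds the regulator CsrA, had 50161 FPKM with chromosomal PABP (55471 fragments), 17594 without PABP (18475 fragments) and 17136 with the plasmid. Levels with the plasmid come from a table scaled by 1.02 times on the shared control. For glmY and glmZ no counting interval is given.

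The regulator gene araC was higher in both PABP libraries, at 65.6 and 53.6 FPKM against 9.88, and the design text names pBAD for the plasmid strain. The prophage gene borD, which has a relative in phage lambda, was lower in both, at 8.78 and 41.9 FPKM against 191.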
